A study of Mus musculus with 10 samples.

How the data were processed

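RNA from 10 pools of whole hearts of female mouse embryos at 13.5 days post coitum was hybridised to Affymetrix arrays, 5 pools of Hccs heterozygous heart-conditional knockouts and 5 of control littermates, with 4 to 5 hearts in each pool. Per the labels' protocols, total RNA was purified on spin columns with a DNase step, and 5 ug of it was made into biotinylated cRNA. The deposited values are log2 probe set signals, and per the submitters' processing notes RMA and Partek were used. RMA summarises the probes of each probe set and brings the arrays to a common distribution, and the notes give neither versions nor the background option, so how far low signals were compressed is unknown. The log2 scale was read from the values, which ran from 0.602 to 16.6 with nearly equal quantiles in all 10 arrays, none missing and none below 0. Genotypes came from the labels of each sample, and every column of the table was used. Because the arrays were brought to a common distribution, a change of total RNA per heart cannot be seen, and a rise of some transcripts is relative to the others. Signal over background was not given, so detection calls were not made. The labels give no hybridisation or scan batch.

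Of 45101 probe sets 64 were array controls, 34945 carried 1 gene symbol, 932 several and 9160 none. Symbols come from the platform annotation, and 34741 of the probe sets with 1 symbol were found by Entrez gene number in the RefSeq table of assembly GRCm38.p6, which changed 0 symbols. That table also gave chromosomes, gene spans and the order of neighbouring genes, and no coordinates are printed, since the build of the array annotation is not given in the sources used here. Control probe sets and those with no or several symbols were left out, and the probe set with the highest mean over all arrays stood for a gene, giving 18193 genes. List genes without such a probe set, among them Gdf15, Pycr1, Gapdh, Bax and Ccnb1, were not analysed here.

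Log2 changes are knockout minus control, fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, genotype as the only term, two-sided). P-values were adjusted over all genes by the Benjamini-Hochberg method with a threshold of 0.05, and no filter on low values was used. A standard error is that of the moderated fit. Single values, such as Hccs, list scores and array measures, were compared by an exact two-sided permutation test over all splits of the arrays. Gene lists were tested with camera with a preset correlation of 0.01 between genes, adjusted over the 37 lists, and beside it with camera with an estimated correlation and with fry. Camera sets a list against all other genes, and fry asks only whether its genes move 1 way on balance. A list score is the mean deviation of the members from their means over the 10 arrays.

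The tests, the 37 lists, the rule for named genes and, but for 3 named below, the alternatives were fixed before the data were examined. The lists cover cytochrome c and its haem lyase, haem synthesis, complexes I, II and III, IV and ATP synthase, mitochondrial ribosomal proteins, the citric acid cycle, fatty acid oxidation, glycolysis, hypoxia targets, ATF4 targets, tRNA synthetases, mitochondrial chaperones, endoplasmic reticulum stress, autophagy, NRF2 targets, p53 targets, G1/S, G2/M and cell cycle inhibitors, sarcomere, load and stress, cardiac transcription factors, 10 lists of other cell types, interferon response, cholesterol synthesis and sex. Named are Hccs; the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap and whose higher group mean lay above the 40th percentile of mean levels; up to 4 members of each list with the smallest p among those that passed, with the brightest member that did not as a contrast; and the 3 brightest members of each list of another cell type. Names outside this rule are marked as chosen after their values were seen.

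In a single simulation with the spread of these arrays, 53.7%, 79.1% and 95.5% of genes changed by 0.3, 0.5 and 1 log2 units were found, with 11 false calls of 163 over 18193 genes. Only 200 genes were changed there and all genes were drawn independently, so these rates may not hold for the real arrays. In 101 simulated lists of 20 genes camera called the 1 shifted list and none of 100 unshifted lists; these genes were drawn independently, unlike real genes. The alternatives were the replicate number as a block, quantile normalization, median centring, filters at the median and the lower quartile of mean level, the mean of a gene's probe sets, the most variable probe set, every probe set, eBayes with trend and robust, array weights, stricter thresholds, and each array left out in turn. Added after seeing the data were the arrays numbered 3 of both genotypes left out, a lowess trend on gene span removed array by array, and the mean of the hybridisation controls as a covariate. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.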

Results

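Gene expression was measured on Affymetrix arrays in whole hearts of female mouse embryos at 13.5 days post coitum. Embryos heterozygous for a heart-conditional knockout of Hccs were compared with their control littermates. Hccs encodes the mitochondrial enzyme that attaches haem to cytochromes c and c1, and it lies on the X chromosome. Because 1 X chromosome is inactivated in each female cell, a heterozygous female heart is a mosaic of cells with and without the enzyme. There were 5 biological replicates per genotype, each a pool of 4 to 5 hearts of 1 genotype on 1 array. Per the series description, tissue composition changes most at this stage, with strong division of healthy cardiomyocytes while many cells lacking the enzyme remain. The comparison therefore asks how the transcripts of the whole mosaic heart differ from those of a control heart. The table held 45101 probe sets per array with log2 signals from 0.602 to 16.6. Array medians lay between 3.65 and 3.76, and the number of arrays limits the precision.

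Hccs transcript was lower in every knockout pool than in any control pool. The log2 signal of the brighter probe set was 11.23 ± 0.08 in controls and 10.68 ± 0.20 in knockouts (mean ± SD, n = 5 each), and the exact two-sided permutation p was 0.00794, the smallest that 5 against 5 arrays allow. The signal fell by 31.7%, a log2 change of -0.55 (SE 0.090, limma adjusted p = 0.0225 over 18193 genes). The dimmer Hccs probe set fell by 24.3%, from 9.18 ± 0.08 to 8.78 ± 0.25, with the same exact permutation p and a limma adjusted p of 0.105 over all probe sets. Where the probes lie relative to the deleted part of the gene is not given in the sources used here, so the size of this decrease does not measure the share of recombined cells. Without control replicate 2, control replicate 3, knockout replicate 2 or knockout replicate 4, the limma adjusted p of Hccs rose to 0.0511, 0.0511, 0.0517 and 0.0563. With the arrays numbered 3 of both genotypes left out together it was 0.0714, with a log2 change of -0.59. Over all alternatives the adjusted p ran from 0.00976 to 0.0735.

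**Figure D1:**
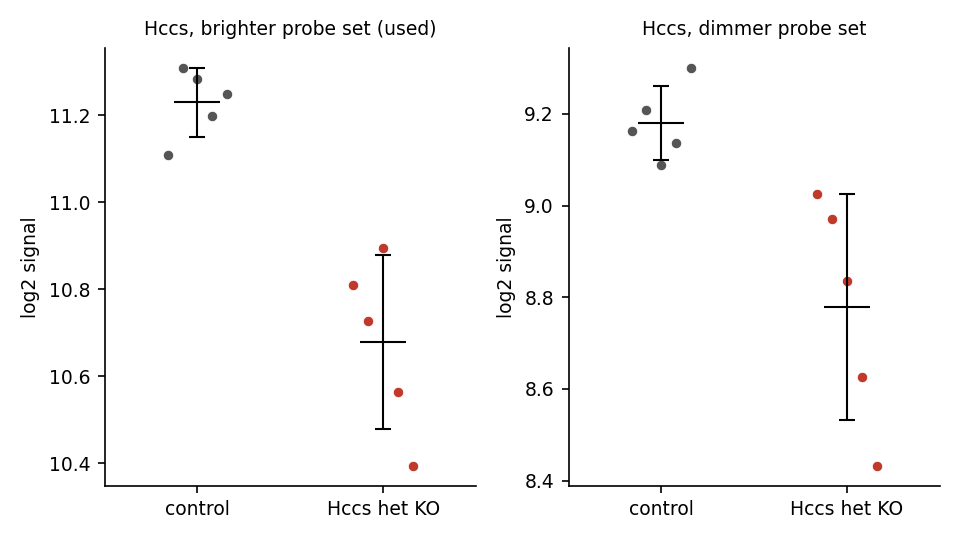
Log2 signal of the Hccs probe sets (vertical axes, which do not start at 0) in each control and heterozygous knockout pool, 5 points per genotype, with horizontal bars at the mean and error bars of 1 SD; sideways position has no meaning. In the brighter probe set the 5 control pools lie between 11.1 and 11.3 and the 5 knockout pools between 10.4 and 10.9.

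Across the genome 469 of the 18193 genes passed an adjusted p of 0.05, 297 of them higher and 172 lower in the knockout hearts. An unadjusted limma p under 0.05 was reached by 3753 of the 18193 genes. Unadjusted counts in the lists below are to be read against that share. The 12 largest rises are given among genes with fully separated groups and a level above the 40th percentile. Slc7a3, a cationic amino acid transporter, rose from a log2 signal of 3.81 ± 0.47 to 7.31 ± 0.33 (mean ± SD, n = 5 each). Chac1, which degrades glutathione, and Trib3, a pseudokinase induced by cellular stress, rose 5.58-fold and 5.50-fold. Asns, asparagine synthetase, rose 4.00-fold, and Cth, which makes cysteine from cystathionine, rose from 3.08 ± 0.46 to 5.09 ± 0.19. Nmrk2, a nicotinamide riboside kinase, rose 2.95-fold, and Mthfd2, a mitochondrial folate enzyme, rose 2.82-fold. The others were Eda2r, a receptor of the tumour necrosis factor receptor family (2.74-fold), Esm1, a proteoglycan secreted by endothelium (from 3.99 ± 0.09 to 5.42 ± 0.61), Pmaip1, a pro-apoptotic protein of the Bcl-2 family (2.54-fold), the transcription factor Atf5 (2.53-fold) and Ccdc89 (from 3.78 ± 0.15 to 5.09 ± 0.63). The control signals of Slc7a3, Cth, Esm1 and Ccdc89 lay near or below the array medians and the signal of the Y-linked Uty in these female hearts (3.66 in controls), so no fold is given for them and their place among the rises is uncertain. Those of Nmrk2 and Chac1, 4.16 and 4.32, were little higher, so the sizes of these rises are uncertain too.

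The 12 largest falls were smaller. Kbtbd11 had a log2 change of -1.14, Ankrd63 of -1.09 and Rbfox2, a splicing regulator, of -0.90. Tbc1d24 had a log2 change of -0.84, Apold1, an endothelial gene, of -0.82 and Per1, a circadian clock gene, of -0.81. The kinase gene Alpk2 changed by -0.81, Dgkk, a diacylglycerol kinase, by -0.79 and Dusp26, a phosphatase, by -0.78. Nkx2-5, a homeobox transcription factor of the cardiac lineage, fell by 41.7%, from 11.17 ± 0.11 to 10.39 ± 0.19 (log2, mean ± SD, n = 5 each, limma adjusted p = 0.0108). Eme2 and Klhl41, the latter a kelch protein of striated muscle, had log2 changes of -0.78 and -0.76. For Kbtbd11 only 1 of 4 probe sets, for Rbfox2 2 of 4, for Tbc1d24 1 of 3 and for Eme2 2 of 3 pointed down, and the rest did not. The knockout signals of Ankrd63 (3.28) and Per1 (3.68) lay near or below the array medians, so the sizes of these 2 falls and their place among the 12 are uncertain.

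The first principal component held 29.2% of the variance and separated the genotypes (exact permutation p = 0.00794, n = 5 each). Of the 469 genes, 439 had groups that did not overlap; over all genes 5.79% did, where chance gives 0.794%. The signal of the 18S ribosomal RNA 5' control probe set, a sign of residual ribosomal RNA, was also lower in the knockouts (10.05 ± 1.25 against 8.17 ± 0.35, exact permutation p = 0.0238, n = 5 each), and control replicate 3, at 8.06, lay among the knockouts. The count changed when 1 array was left out, which also lowers the power of the test. It was 116, 170, 111 and 177 without control replicate 1, 2, 3 and 4, and 1042, 120, 147, 105 and 210 without knockout replicate 1, 2, 3, 4 and 5. Without the arrays numbered 3 of both genotypes it was 30, of which 29 were among the 469. Of the 57 named genes past the threshold, 17 passed in all 10 fits with 1 array left out and the others lost their call in at least 1, with no change of direction. The 17 were Asns, Ccng1, Chac1, Cth, Eda2r, Fas, Kbtbd11, Mars1, Mthfd2, Nars, Nkx2-5, Nmrk2, Phgdh, Phlda3, Rbfox2, Slc7a3 and Trib3.

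Among the 15 lists called, the largest mean log2 change, 0.74, was that of genes induced by the transcription factor ATF4 and by amino acid shortage. Of 35 measured members 20 rose, none fell and 15 did not pass, and 25 rose and 1 fell when adjusted over the list alone. The median log2 change was 0.51. Asns rose from 9.92 ± 0.07 to 11.92 ± 0.20 and Phgdh, the enzyme that commits carbon to serine synthesis, from 11.29 ± 0.12 to 12.17 ± 0.08 (log2, mean ± SD, n = 5 each). Slc7a3 went from 3.81 ± 0.47, close to the array median, to 7.31 ± 0.33, and Mthfd2 from 8.35 ± 0.10 to 9.84 ± 0.26. Atf4 itself, chosen after its value was seen, rose 1.47-fold. Eif4ebp1, a repressor of translation and the brightest member that did not pass, had a log2 change of 0.094 (SE 0.050). The mean of the list was higher in all 5 knockout arrays than in any control (exact permutation p = 0.00794, n = 5 each). Camera, limma's competitive gene set test, gave an adjusted p of 4.58e-18 with the preset correlation and an adjusted p of 0.0435 with an estimated correlation. In splits of the arrays other than the real one, camera with the preset correlation called a median of 8 lists. Its adjusted p with that correlation, here and below, therefore cannot be read as error rates. Without the arrays numbered 3 of both genotypes 11 members passed.

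The list of cytosolic tRNA synthetases, which charge tRNAs with amino acids, was higher in the knockout hearts as a group. Of 19 measured members 7 rose and 12 did not pass, all 19 had a positive log2 change, and 12 rose when adjusted over the list alone. The median log2 change was 0.24. Nars rose 1.34-fold, Mars1 1.31-fold, Cars 1.59-fold and Farsb 1.35-fold, while Hars had a log2 change of 0.038 (SE 0.055). Camera gave an adjusted p of 2.61e-08, and an adjusted p of 0.0435 with an estimated correlation. Fewer members passed in most fits with 1 array left out, which also lowers the power of the test. The number was 4, 3 and 4 without control replicate 1, 3 or 4, and 3, 4, 2 and 4 without knockout replicate 2, 3, 4 or 5. It was 2 without the arrays numbered 3.

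The list of p53 targets and apoptosis genes was also higher as a group. Of 18 measured members 7 rose, none fell and 11 did not pass; adjusted over the list alone, 9 rose and 1 fell. Eda2r rose from 5.11 ± 0.14 to 6.56 ± 0.25 and Ccng1, a cyclin induced by p53, from 12.27 ± 0.09 to 12.86 ± 0.12 (log2, mean ± SD, n = 5 each). Phlda3, an inhibitor of Akt signalling, rose 1.26-fold and Fas, a death receptor, 1.47-fold. Plk2 had a log2 change of 0.0075 (SE 0.14). Pmaip1, a member of this list, is also known as a target of ATF4. The median log2 change was 0.28, and camera gave an adjusted p of 0.000311, with an adjusted p of 0.0435 with an estimated correlation. The number of members that passed was 4 without control replicate 1, 4 without knockout replicate 4 and 3 without the arrays numbered 3.

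Genes of the cardiomyocyte sarcomere and of calcium handling were lower in the knockout hearts as a group. All 22 measured members had a negative log2 change, 5 fell and 17 did not pass, and 18 fell when adjusted over the list alone. The median log2 change was -0.23. Tnnc1, cardiac troponin C, fell by 0.30 on the log2 scale (SE 0.049), Atp2a2, the calcium pump of the sarcoplasmic reticulum, by 0.29 (SE 0.049), Myh7, the slow myosin heavy chain, by 0.47 (SE 0.082) and Myl2, the ventricular myosin light chain, by 0.23 (SE 0.042). Tnni1, the fifth that passed and chosen after its value was seen, had a log2 change of -0.30. Actc1, cardiac actin and the brightest member that did not pass, had a log2 change of -0.13 (SE 0.033), and Myh6, also chosen after its value was seen, of -0.051 (SE 0.10). The list mean was lower in all 5 knockout arrays than in any control (exact permutation p = 0.00794, n = 5 each). The 18S signal was lower in the knockouts too, but the list score did not fall with it among the controls. In control replicates 1 to 5 the 18S signals were 9.88, 10.6, 8.06, 10.3 and 11.4. The list scores were 0.11, 0.28, 0.26, 0.13 and 0.028. Whether 18S carry-over lowered the list was not tested further. Genes called lower over the whole genome had a median span of 51.7 kb against 17.7 kb for genes called higher. The median span of the sarcomere list lay nearer to the 20.3 kb of all genes than to 51.7 kb. Camera gave an adjusted p of 7.89e-16, and an adjusted p of 0.0435 with an estimated correlation. The number of members that passed was 1, 1, 1 and 3 without control replicate 1, 2, 3 and 4, 1, 1 and 0 without knockout replicate 2, 3 and 4, and 0 without the arrays numbered 3.

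**Figure D2:**
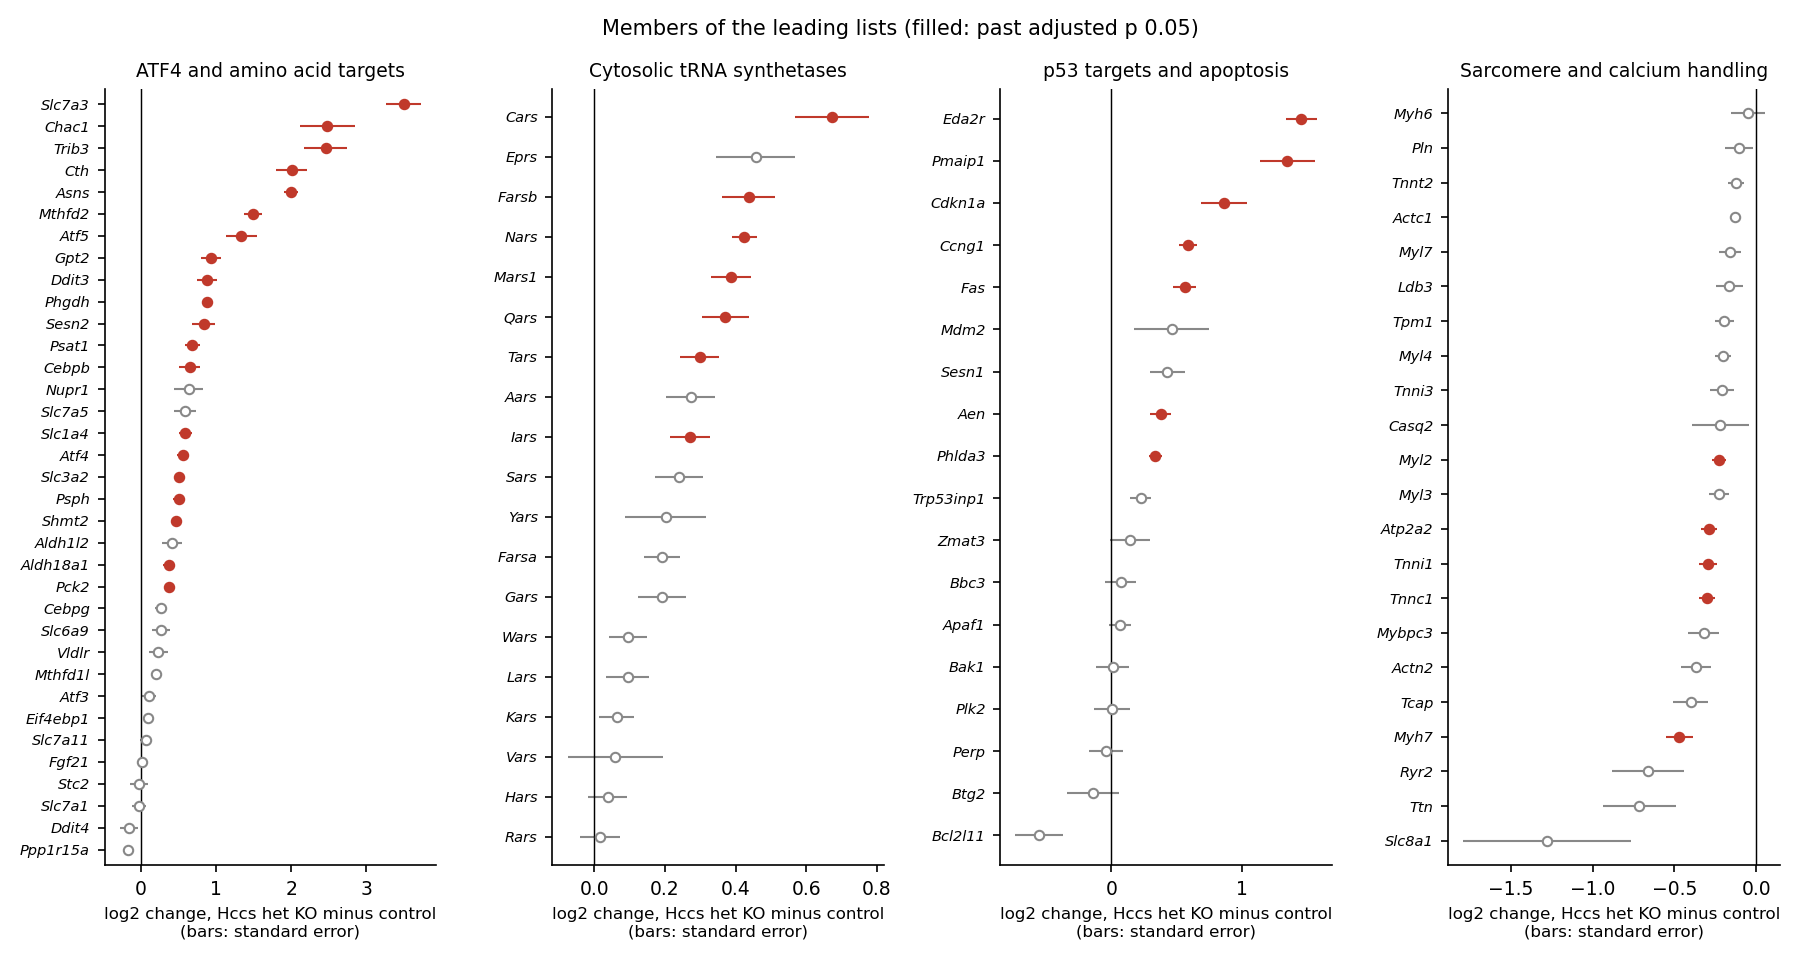
Log2 change (knockout minus control, horizontal axes with different ranges) of every measured member of the ATF4, tRNA synthetase, p53 and sarcomere lists, with bars of 1 standard error; filled red points passed an adjusted p of 0.05 over all genes. In the ATF4 panel 20 of 35 members are filled, all to the right of 0, and in the sarcomere panel all 22 members lie to the left of 0, with 5 filled.

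Of 18 cardiac transcription factors Nkx2-5 fell and the others did not pass; Tbx20 had a log2 change of -0.14 (SE 0.078). Adjusted over the list alone, 1 rose and 1 fell. Nkx2-5 is a gene often used to drive Cre recombinase in the heart, and the driver of this knockout is not given in the sources used here. Camera gave this list an adjusted p of 0.0207, lost with an estimated correlation (adjusted p = 0.269), and an adjusted p of 0.0608 without control replicate 2. None of 9 genes of cardiac load and stress passed in limma, while 4 had an unadjusted p under 0.05 and 3 fell when adjusted over the list alone. Camera's adjusted p for them was 0.104, and without knockout replicate 2 or 5 it was 0.0465 and 0.0407, a call in the lower direction.

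Among the partners of the enzyme, Cycs, somatic cytochrome c, rose 1.27-fold (15.03 ± 0.10 to 15.37 ± 0.11, log2, mean ± SD, n = 5 each, limma adjusted p = 0.0294), while Cyc1, cytochrome c1, had a log2 change of -0.18 (SE 0.067, limma adjusted p = 0.17) and did not pass. In this list of 4 genes Hccs fell and Cycs rose, and 2 did so in each direction when adjusted over the list alone (camera adjusted p = 0.74). None of 9 measured genes of haem synthesis passed in limma, over all genes or adjusted over the list alone, and 1 had an unadjusted p under 0.05 (camera adjusted p = 0.525).

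Of 34 measured complex I subunits Ndufb7 fell (log2 change -0.19, SE 0.036), while Ndufb6 had a log2 change of 0.37 (SE 0.087) and did not pass; adjusted over the list alone, 1 rose and 2 fell. Of 13 complex II and III subunits only Uqcrc2 rose (0.34, SE 0.072), also when adjusted over the list alone, while Uqcrb had a log2 change of -0.11 (SE 0.043). None of 12 complex IV subunits passed in limma, 7 had an unadjusted p under 0.05, and 6 fell and 1 rose when adjusted over the list alone. Of 15 ATP synthase subunits Atp5j fell (-0.14, SE 0.026), 8 fell when adjusted over the list alone, and Atp5h had a log2 change of 0.084 (SE 0.045). With 1 array left out, 0 to 3 complex I and 0 to 1 complex II and III subunits fell past the threshold. For complex IV it was 0 to 3 and for ATP synthase 0 to 6, so these counts changed with the arrays kept. The medians of the 4 lists were -0.029, -0.081, -0.10 and -0.13. Camera with the preset correlation called all 4 lower, with adjusted p of 0.00798, 0.0488, 0.00986 and 5.16e-06. The estimated correlations were 0.41, 0.51, 0.43 and 0.42 against the preset 0.01, and each call was lost with them (adjusted p = 0.697, 0.697, 0.633 and 0.317). Some of these calls were lost with 1 array left out, while that of ATP synthase was kept with each array left out. The ATP synthase score was lower in all 5 knockout arrays than in any control (exact permutation p = 0.00794, n = 5 each). The complex I call was lost without control replicate 2 (adjusted p = 0.0608) and knockout replicates 3 and 5 (0.0788 and 0.0586), and the complex IV call without knockout replicate 3 (0.0708). That of complexes II and III was lost without control replicate 2, 4 or 5 (0.117, 0.0608 and 0.157) and without knockout replicate 3 or 5 (0.233 and 0.109).

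Of 76 mitochondrial ribosomal proteins 4 rose and 72 did not pass, and 8 rose when adjusted over the list alone. With 1 array left out 0 to 6 rose, and it was 0 without control replicate 1. Mrps9 had a log2 change of 0.40 (SE 0.080), Mrps23 of 0.38, Mrpl9 of 0.31 and Mrpl15 of 0.20, while Mrpl42 had 0.050 (SE 0.071). The list median was 0.049, with an adjusted p of 0.0291 by camera and an adjusted p of 0.762 with an estimated correlation. The call was also lost without control replicates 1 and 3 and knockout replicate 1 (adjusted p = 0.0723, 0.253 and 0.17). Mrps9 pointed the other way when the most variable probe set stood for it (log2 change -0.48, not past the threshold). Of 16 mitochondrial chaperones and proteases Hspa9, the import motor chaperone, rose (0.34, SE 0.073), 0 to 2 rose with 1 array left out, 7 rose when adjusted over the list alone, and Hspd1 had a log2 change of -0.039 (SE 0.047). The camera adjusted p of that list was 0.00867, and 0.289 with an estimated correlation. Fry gave it an adjusted p of 0.00651 in the higher direction, and the mitochondrial ribosomal proteins 0.351. The score of the chaperone and protease list was higher in all 5 knockout arrays than in any control (exact permutation p = 0.00794, n = 5 each).

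Among genes of fuel use, 2 of 15 glycolytic genes fell, Tpi1 (log2 change -0.31, SE 0.065) and Pgk1 (-0.22, SE 0.049), while Ldha had -0.14 (SE 0.036) and did not pass; adjusted over the list alone, 4 fell and 1 rose. Of 16 hypoxia (HIF) targets Mxi1 (-0.29, SE 0.047) and Egln3 (-0.43, SE 0.084) fell, 6 fell when adjusted over the list alone, and the glucose transporter Slc2a1 had a log2 change of -0.0027 (SE 0.13). With 1 array left out 0 to 2 glycolytic genes and 0 to 3 hypoxia targets fell. Camera called both lists lower (adjusted p = 0.000137 and 0.000171), and both calls were lost with an estimated correlation (adjusted p = 0.289 for each). Of 21 fatty acid oxidation genes only Hadhb rose (0.59, SE 0.11), against the direction of its list, and 2 rose when adjusted over the list alone. Of the 3 probe sets of Hadhb 1 pointed up, and it pointed down, without passing, in their mean (-0.032) and in the most variable of them (-0.66). The list had a median of -0.075, Hadh a log2 change of -0.040 (SE 0.073), and camera an adjusted p of 0.0379, lost with an estimated correlation (adjusted p = 0.697). It was also lost without control replicates 2 and 5 and knockout replicates 3 and 5 (adjusted p = 0.171, 0.0657, 0.16 and 0.378), with a mean of 0.013 in the last. None of 15 citric acid cycle genes passed in limma, also when adjusted over the list alone, and 3 had an unadjusted p under 0.05 (camera adjusted p = 0.74).

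Of 21 G1/S cell cycle genes Mcm4, a replicative helicase subunit, rose 1.55-fold and Ccne2, cyclin E2, rose 1.36-fold, while Pcna had a log2 change of -0.0095 (SE 0.057); 3 rose when adjusted over the list alone. None of 21 G2/M genes passed over all genes in limma, 7 had an unadjusted p under 0.05, and adjusted over the list alone 2 rose and 2 fell. Of 14 cell cycle inhibitors Cdkn1a, p21 and also a p53 target, rose 1.82-fold, 2 rose when adjusted over the list alone, and Cdkn1c had a log2 change of -0.16 (SE 0.073). With 1 array left out 0 to 2 G1/S genes and 0 to 2 inhibitors rose. Camera called none of these lists, with adjusted p of 0.217, 0.587 and 0.587, but the G1/S list was called higher without knockout replicate 2 (adjusted p = 0.0493).

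Of 19 endoplasmic reticulum chaperones and stress genes Herpud1 rose (1.30-fold), also when adjusted over the list alone, while Calr had a log2 change of -0.20 (SE 0.0998). Of 15 autophagy genes Map1lc3a fell (log2 change -0.41, SE 0.065), while Gabarap had -0.12 (SE 0.062), and 1 rose and 1 fell when adjusted over the list alone. With 1 array left out 0 to 2 of the former rose and 0 to 1 of the latter fell. No member passed in limma, over all genes or adjusted over the list alone, among 14 NRF2 targets, 10 interferon response genes and 13 cholesterol synthesis genes, of which 2, 0 and 3 had an unadjusted p under 0.05. Camera's adjusted p for these 5 lists was 0.796, 0.139, 0.74, 0.359 and 0.248. The autophagy list was called lower without knockout replicate 4 (adjusted p = 0.0499).

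None of the lists of other cells of the heart was called. Of 11 epicardial genes Tcf21, a transcription factor of epicardium-derived cells, rose 1.52-fold, also when adjusted over the list alone, though only 1 of its 2 probe sets pointed up; Upk3b and Tbx18 had log2 changes of 0.069 and 0.18. No gene passed in limma among 14 of endothelium and endocardium (Emcn 0.13, Tek 0.023, Npr3 -0.19), 15 of mesenchyme, valve and matrix (Col3a1 0.012, Postn -0.10, Col1a2 -0.099), 9 of smooth muscle (Acta2 -0.13, Tagln -0.20, Cnn1 -0.27), 9 of erythroid cells (Hbb-y -0.088, Hba-x -0.29, Hbb-bh1 0.29) and 12 of leukocytes (Csf1r -0.049, Lyz2 -0.42, C1qb 0.51). Of these lists 5, 2, 4, 1 and 2 members had an unadjusted p under 0.05, as did 3753 of all 18193 genes. Adjusted over the list alone, 1 smooth muscle gene rose and 3 fell, and no member of the other 4 lists passed. Camera's adjusted p was 0.406 for epicardium, 0.0568 for endothelium, 0.456 for mesenchyme, 0.215 for smooth muscle, 0.217 for erythroid cells and 0.74 for leukocytes. The endothelial list, with a median of -0.12, was called lower without control replicate 4 (adjusted p = 0.00743) and without knockout replicate 1 (0.032). Median, mean and direction of the test differed in sign in the lists of cytochrome c, haem synthesis, the citric acid cycle, G2/M, cell cycle inhibitors, load and stress, mesenchyme, smooth muscle, leukocytes and sex, none of which was called.

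Markers of tissue next to the heart varied from pool to pool. The nerve and neural crest list had a score, the mean deviation of its members from their means over the 10 arrays, of 1.68 in control replicate 3 and at most 0.35 elsewhere. It was called lower in the knockouts (7 of 7 members negative, camera adjusted p = 0.0215), but no member passed in limma, over all genes, over the list alone or at an unadjusted p under 0.05. The call was lost with an estimated correlation (adjusted p = 0.502) and without control replicate 3 (adjusted p = 0.0563), where the mean log2 change went from -0.59 to -0.24. Stmn2, Dbh and Sox10 had log2 changes of -0.96 (SE 0.54), -0.17 (SE 0.19) and -0.17 (SE 0.15). Liver markers had scores of 2.01 and 1.57 in knockout replicates 4 and 5, and markers of lung and other epithelium a score of 2.01 in knockout replicate 3. None of 10 liver, 9 lung and 11 skeletal muscle genes passed in limma, over all genes or over the list alone, and 0, 0 and 4 had an unadjusted p under 0.05 (camera adjusted p = 0.74, 0.619 and 0.666). Afp, Ttr and Apoa1 had log2 changes of 0.41 (SE 1.18), 0.22 (SE 1.04) and -0.54 (SE 1.45), Sox2, Cdh1 and Krt5 of 1.48 (SE 0.91), 0.79 (SE 0.98) and -0.26 (SE 0.52), and Acta1, Ckm and Myh3 of -0.35 (SE 0.10), -1.16 (SE 0.41) and -1.59 (SE 1.04). The Y-linked Eif2s3y, Uty and Kdm5d averaged 2.86, 3.66 and 2.67 in controls and 2.94, 3.78 and 2.70 in knockouts, near or below the array medians. Xist, the RNA of the inactive X chromosome, was at 11.48 ± 0.49 in controls and 10.78 ± 0.27 in knockouts (log2, mean ± SD, n = 5 each, limma adjusted p = 0.135), and was the 1 gene of these 4 that passed when adjusted over the list alone (camera adjusted p = 0.881).

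**Figure D3:**
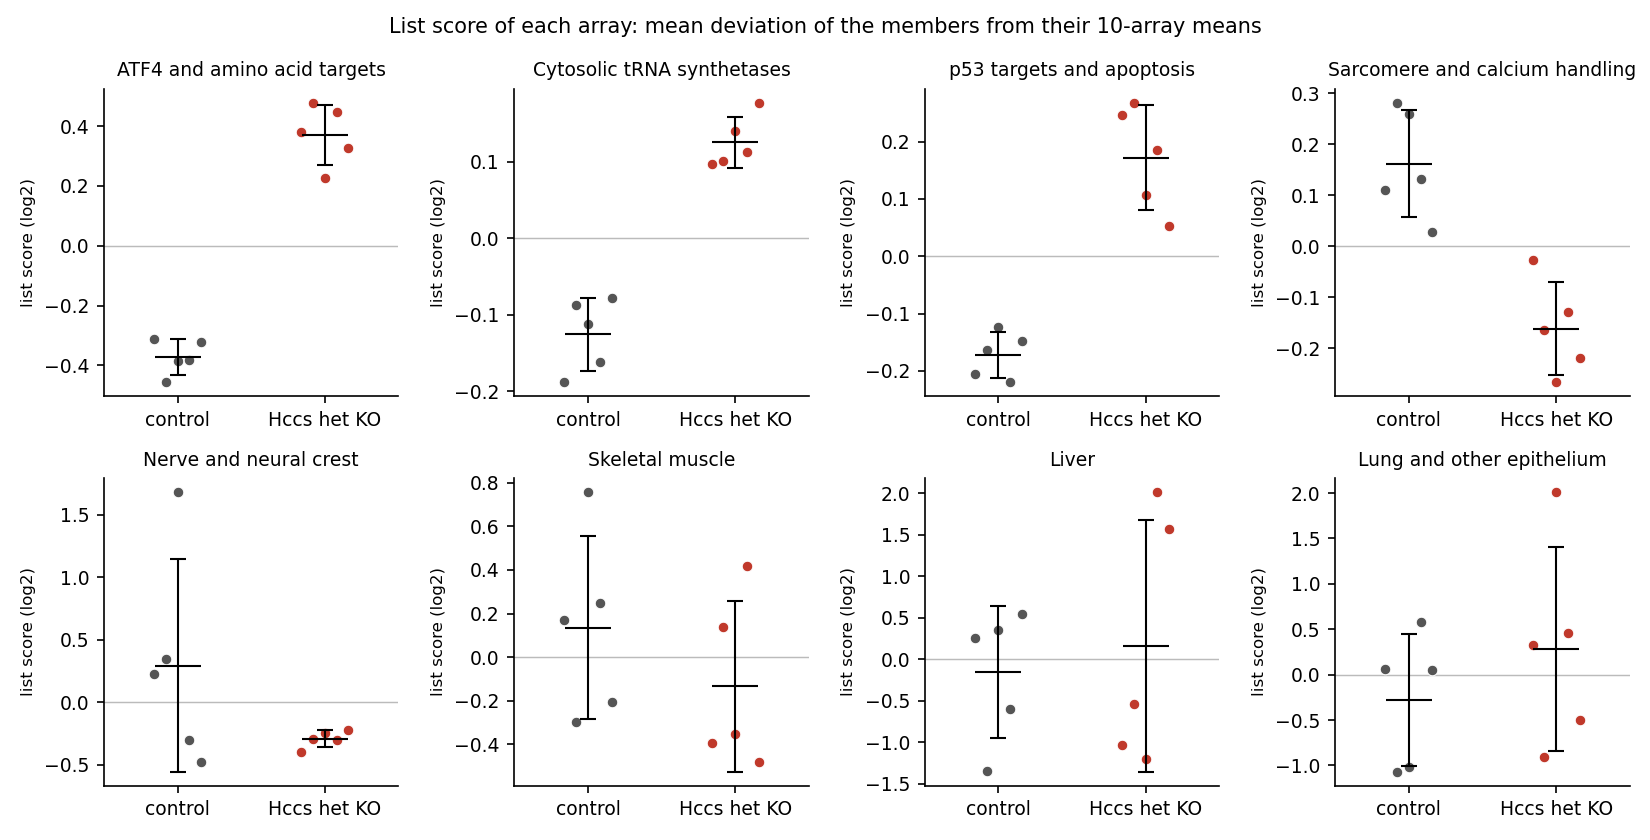
List score of each array (vertical axes in log2 units with different ranges), the mean deviation of a list's members from their means over the 10 arrays, with 5 points per genotype, horizontal bars at the mean and error bars of 1 SD; sideways position has no meaning. In the upper row, the ATF4, tRNA synthetase, p53 and sarcomere lists, the genotypes do not overlap; in the lower row, markers of tissue next to the heart, single pools stand apart, as control replicate 3 with a nerve score of 1.68.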

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

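The tests on splits of the arrays were fixed before their results were seen; those on the sarcomere list, gene spans and control replicate 3 were chosen after. Of the 126 splits of the 10 arrays into 5 and 5, 100 were run, the real one included. Only the real one gave as many genes past the threshold as the real genotypes, which gave 469, and the highest other split gave 3. This argues against chance for the gene count at the level of 1 in 100, and does not exclude it. Every other split mixed the genotypes, which can widen the spread within groups and lower its count. A preparation difference that follows genotype would give the same result, so the splits cannot separate it from genotype. For the number of lists called with the preset correlation, 8 of 100 splits gave at least the 15 of the real genotypes. The highest other gave 16 and the median other 8, so chance is not excluded for that number. Every other split with 16 lists, and most with 15, kept 4 arrays of 1 genotype together. Those splits carried much of the genotype difference, so this comparison decides little either way. With an estimated correlation 4 lists were called, and splits were not run for that number.

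The sarcomere list was weighed against technical trends. Its median of -0.23 lay at percentile 0 of the medians of 10000 random lists matched on brightness, whose central 95% ran from -0.10 to 0.06. Their median was -0.023, so other genes as bright did not fall as much, which argues against compression of bright signals as the whole cause. The random lists were drawn gene by gene, while sarcomere genes vary together (estimated correlation 0.22), so the percentile is not a chance level. With the trend on gene span removed the mean was -0.34 against -0.32 before, and the call was kept (exact permutation p of the list score 0.00794, n = 5 each), which argues against that trend as the whole cause. A lower share of cardiomyocyte RNA would raise the markers of other heart cells alike. The scores changed by -0.092 for endothelium, 0.16 for epicardium, 0.0057 for mesenchyme and 0.063 for smooth muscle (exact permutation p = 0.127, 0.23, 0.944 and 0.579), with no clear joint rise. Epicardium minus endothelium was higher by 0.25 in the knockouts (exact permutation p = 0.151), but this difference would also be near 0 if no share changed. At this spread a lower share and lower transcript levels within cardiomyocytes cannot be told apart with these pools. The genotype itself, with cells lacking the enzyme in the mosaic heart, stays open as a biological explanation and was not tested.

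Genes called lower had longer spans than genes called higher, with medians of 51.7 and 17.7 kb (permutation p = 1e-05, the smallest that 100000 permutations can give; genes are not independent replicates). The median span of all genes was 20.3 kb. A span is the length of a gene on the genome and not of its transcript. Whether lower RNA integrity in the knockouts would give such a trend is therefore unknown. The 3' minus 5' signal of the actin controls differed by -0.044 and that of the Gapdh controls by -0.031 (exact permutation p = 0.222 and 0.0952, n = 5 each). These differences decide nothing at this spread, though lower integrity would raise both. The rank correlation of an array's deviations with span, across genes, was 0.092 ± 0.195 in controls and -0.0969 ± 0.0708 in knockouts (mean ± SD) with an exact permutation p of 0.0794, and control replicate 5, at -0.240, lay below every knockout (-0.215 to -0.0338). Whether the trend belongs to the genotype or to single arrays therefore cannot be told apart. With the trend removed 465 genes passed, of which 400 were among the 469.

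Control replicate 3 stood apart, with the lowest value on the first principal component (-31.0) and the lowest median correlation with the other arrays (0.991). A mislabelled knockout pool is argued against by its ATF4 score of -0.39, among the other controls (-0.46 to -0.31) and below every knockout (0.23 to 0.48). RNA of neighbouring tissue in the pool may account for part of it and stays open: 8 of 16 nerve and skeletal muscle markers were highest in this array, but this test was chosen after the list scores were seen, Acta1 and Ckm, which the heart also expresses, were left out after their values were seen, and markers of a tissue vary together, so the count decides nothing. Among them Myh3 had a signal of 10.8, Stmn2 of 9.58 and Tubb3 of 8.02, against at most 9.25, 8.11 and 5.30 in any other array, while Myod1 and Pax7 were not highest there. No biological explanation was tested for this pool.

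In 282 groups of 5 values, of named genes and list scores, 19 held 1 array far from the other 4, where chance gives 14.1, so most of these need no explanation. Among list scores they were ATP synthase and autophagy in control replicate 5 (0.13 and 0.11), glycolysis in control replicate 4 (-0.025), leukocytes in control replicate 3 (-0.30) and mesenchyme in knockout replicate 5 (0.12). Control replicate 4 was low for Nmrk2 (3.87) and Eda2r (4.86). Control replicate 3 was low for Esm1 (3.82) and Csf1r (9.80) and high for Hspd1 (14.4). Control replicate 5 was high for Ankrd63 (4.51) and Pgk1 (14.8), and control replicate 1 was low for Eif4ebp1 (12.7) and Hspa9 (12.6) and high for Krt5 (7.13). Knockout replicate 1 was low for Per1 (3.08), knockout replicate 3 for Ndufb7 (12.7) and Mrpl42 (13.4), and knockout replicate 5 for Ckm (8.73). Outside the comparisons, 45 of 10092 probe sets with no or several gene symbols passed when every probe set was tested, 31 higher and 14 lower, 22 of them with no symbol and 23 with several.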

How the results depend on the processing

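The arrays numbered 3 left out together, the removed span trend and the hybridisation controls as a covariate were chosen after seeing the data. The labels do not say whether replicate numbers mark shared litters or batches. The data gave no sign of pairing: same-numbered pools correlated at -0.0682, 0.0344, -0.0911, 0.0767 and 0.00975, and 1 of 5 controls correlated best with its own number. With the replicate block 36 genes passed (30 higher, 6 lower), with 7, 1, 2 and 0 members of the ATF4, tRNA synthetase, p53 and sarcomere lists in place of 20, 7, 7 and 5, and Hccs, at -0.55, had an adjusted p of 0.0735 (0.00976 to 0.0735 over its alternatives). The numbers of genes past the threshold, higher and lower, were 759, 475 and 284 with genes under the median level left out (fewer genes tested), 945, 631 and 314 with array weights, 172, 118 and 54 with the hybridisation controls as a covariate, 30, 26 and 4 without the arrays numbered 3 (fewer arrays), 100, 74 and 26 with a fold change of at least 1.5, and 14, 14 and 0 at an adjusted p of 0.01. The lower genes were 108 with median centring and 76 with the mean of all probe sets. With 1 array left out the ranges were 105 to 1042, 73 to 752 and 32 to 290. The stricter thresholds lower these counts by construction. The cause of the other differences was not tested, also where fewer genes or arrays entered, and without knockout replicate 1 the count rose to 1042. Quantile normalization gave 416 genes, of which 371 were shared with the 469, and 55.3% of its calls were higher against 63.3% as deposited; the median change of all genes was 0.025 as deposited, 0.0060 with quantile normalization and 0.041 with median centring.

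Hccs kept its direction in all 23 alternatives, from -0.60 to -0.48 with 1 array left out, and was -0.59 without the arrays numbered 3, where its call was lost. The ATF4, tRNA synthetase, p53 and sarcomere lists kept their calls in all 25 alternatives each, and the other 11 of 15 lost theirs in at least 1. Apart from camera with an estimated correlation and fry, these alternatives used camera's preset correlation, whose adjusted p cannot be read as error rates. For those lists the estimated correlation gave an adjusted p of 0.0435 each. Fry gave them adjusted p of 3.87e-05, 0.000147, 6.8e-05 and 0.00161. Lists called lower numbered 10, and 5 with quantile normalization, 4 and 6 with the filters at the median and the lower quartile, 6 without the arrays numbered 3, 1 with an estimated correlation, 1 with fry and 6 to 11 with 1 array left out. Lists called higher numbered 5, and 3 with an estimated correlation. The fatty acid oxidation list turned to 0.013 without knockout replicate 5, where it was not called (-0.063 to 0.013 with 1 array left out). Mrps9 turned to -0.48 with the most variable probe set, and Hadhb to -0.032 with the mean and -0.66 with the most variable of its probe sets. For the 103 named genes other than Hccs, 1844 of 2350 values kept direction and side of the threshold, 430 lost the call, 13 gained it, these 3 turned, and 60 changed sign without passing in either fit, as did 47 list means. Signal over background was not given, so how far low signals limit these counts is unknown.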

Other observations

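All tests here were chosen after the data were seen. Gene families defined by a shared symbol stem and at least 10 measured members were tested with camera in addition to the fixed lists. Of 219 families 6 were called with the preset correlation, 1 higher and 5 lower, and none with an estimated correlation. The higher family was Mettl, the methyltransferase-like genes, of which 2 of 26 rose (median log2 change 0.12). The lower ones were Atp (77 members), Ppp (79), Myl (11), Chd (10) and Ppm (12), with medians of -0.038, -0.053, -0.16, -0.17 and -0.12, though 1 of the Ppm genes rose. All 6 medians kept their sign with quantile normalization and with median centring. The Myl genes are mostly myosin light chains and overlap the sarcomere list. The Atp genes include the ATP synthase list and Atp2a2 of the sarcomere list. The 2 Atp genes that fell were Atp5j and Atp2a2, both named above, so this family is not a separate result.

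Because Hccs is X-linked and the hearts are mosaic, it was asked as a hypothesis whether X-linked genes changed more often than others. Of 617 X-linked genes 22 passed (3.57%, 14 higher and 8 lower), against 447 of 17414 other genes (2.57%). The odds ratio was 1.40 with a 95% interval of 0.864 to 2.17 and a Fisher's exact p of 0.123, which leaves the question open. The densest run of calls among 51 neighbouring genes lay on the X chromosome, with 7 calls, among them Eda2r and Slc7a3, but a share of 0.431 of 10000 random placements of the calls gave a run as dense, so chance is not excluded.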
